A study of Schizosaccharomyces pombe with 2 samples.

How the data were processed

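Hi-C was done on logarithmic cultures of the sap1-1 strain grown in rich medium, first at 26 °C and then for 6 hours at 33 °C. Cells were fixed in 3% formaldehyde for 20 min. Chromatin was digested with HindIII, and the ends were filled with biotin before ligation. Reads were aligned with Bowtie2 2.1.0 to ASM294v2, per the submitters' processing notes. The series has 2 samples in 1 group and no control, and the values form 1 matrix whose file header carries a tag for replicate 1. Whether the replicates were pooled is not stated, so the map was treated as 1 sample. Raw reads were not used here.

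The deposited values are contact signal per pair of 10 kb bins after iterative correction by the authors, with the diagonal kept. Every one of the 1218 bins with values had the same sum (57251.422 to 57251.495), and 40 bins are blank. The file header gives 37571192 reads. Because iterative correction divides whole read numbers by a factor per bin, the factors and the reads were recovered from the values. Of the values, 99.9% came within 0.05 of a whole number, as did 100% of those under 30 reads, and the recovered reads made 99.9% of the header's total. Poisson intervals at 95% were taken on these reads. Of the recovered reads, 15.6% joined different chromosomes and 13.3% lay within 1 bin. Of the off-diagonal values, 0.516% were 0.

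Genes, LTRs and tRNA genes came from a reference annotation whose 3 chromosome lengths equal those of the file. Centromere midpoints were the middle of the gene-free stretch of each chromosome (39.2, 51.5 and 78.2 kb long). Centromere windows held the bins with values within 50 kb of a midpoint, and end windows the outermost 5 bins with values. Arm bins lay at least 200 kb from a chromosome end and 100 kb from a centromere midpoint. Contact with ends or centromeres of other chromosomes was divided by the running median of bins within 100 kb on each side on the same arm. The ends of III were kept apart, since they border the ribosomal DNA.

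The decay exponent was a least-squares slope of log10 mean contact on log10 separation from 20 to 1000 kb. Contact among members of a list and pairs of arm bins were set against the mean of inter-chromosomal bin pairs in the same 100 kb classes of distance from the centromeres. Boundaries were minima of a 50 kb insulation score, at least 0.1 below the higher flanking maximum. With 1 group and 1 map no test between groups was possible. Values were placed among 10000 seeded random windows, random arm bins matched on arm, or shifted boundaries, and list and window values outside the 2.5th to 97.5th percentile are reported as calls. Chance puts 5% of such values outside.

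The lists were tRNA genes, 5S rRNA genes, Tf2 elements, LTRs, ribosomal protein genes, histone genes, meiotic genes, glycolytic genes, heat shock genes, telomere repeat sites and the mating-type genes, with tlh1 and tlh2 as end-linked helicase genes. Of 49 genes listed by symbol, 44 were found under that symbol. The lists, tests, windows and most alternatives were fixed before the data were examined. The named genes were those nearest the middle of the bin (at most 2), and list members, in 20 arm bins, 10 boundaries and 10 pairs of arm bins. The arm bins were those with the highest ratio among bins above the running median for every end on another chromosome, the boundaries were the deepest, and the pairs had the highest ratio to expectation, with neighbours within 2 bins merged. Members of lists of under 10 genes, sap1 and taz1 were named too. Genes of the right end of I and of bin 2080001 on II were named after their values were seen.

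The plan was changed in these ways. The mat2 genes are absent from the reference used, so the bin of mat3 stood for the region, and its percentile was taken over all 1068 arm bins. Alternatives, and values of medians of windows, used 2000 random placements. The alternatives chosen in advance were another balancing of the matrix, leaving out the 5% of bins with the lowest sums, other windows, thresholds, ranges, summaries, ends and random sets. Added after seeing the data were reads without the correction, end bins sharing sequence left out, the right end of I left out, mat1 included, the mat3 surroundings left out, a wider telomere repeat rule, a fit on AT content, HindIII sites and reads, boundaries deep on both flanks, 2 internal windows as background, and histone genes without their highest pair.

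The steps were tested on simulated data. In 400 simulated bins all values under 30 reads were recovered exactly. All 20 arm bins raised 3 times were found at 2 times the running median, with 0 others. Of 200 random lists, 15 lay outside the 2.5th to 97.5th percentile. All 40 simulated boundaries with contact across them at 0.7 of its level were found within 1 bin, beside 24 other minima. Computations used Python 3.11.15, NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.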

Results

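Chromosome contacts were measured by Hi-C in fission yeast (Schizosaccharomyces pombe) carrying sap1-1, a mutant allele of the gene for Sap1, an essential DNA-binding protein. Hi-C cuts and re-ligates fixed chromatin so that sequenced ligation products report which loci lay close together. The design lists 2 biological replicates in 1 group, with no control strain, so no value here is a difference between strains. The values form 1 contact map of 1258 bins of 10 kb over 3 chromosomes, and whether it pools the replicates is not stated. There was therefore no replicate error, and each SD is a spread over arms, windows or bins. The map held 37526863 recovered reads, each pair of bins counted once, with 7686 to 98119 reads per bin (median 58761.5) and a median of 11 reads per inter-chromosomal bin pair. The 95% Poisson intervals cover counting error of the summed reads only. They leave out the error of the running median, where it was used, and the unequal weight of reads after the correction. They may therefore be too narrow. Coordinates are on ASM294v2 per the labels, and a bin is named by its first base.

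The chromosomes folded mainly within themselves. Within-chromosome contacts made up 84.1% of the off-diagonal signal of chromosome I (SD 3.32 over bins), 80.8% for II (SD 3.49) and 77.1% for III (SD 2.90). Over all bins together the share was 81.6%, and the 3 chromosomes spread around their own mean with an SD of 3.54. Contact within arms fell with separation, from a mean corrected value of 5084 at 10 kb to 483 at 90 kb and 20.9 at 1000 kb. The decay exponent from 20 to 1000 kb was -1.28 ± 0.036 (SD, n = 6 arms). It was steepest on the left arm of III (-1.34) and shallowest on the right arm of I (-1.24). The left arm of III is 1104 kb long, so its longest separations join bins near the centromere to bins near the end. The slope was not constant over the range, being -1.16 from 20 to 100 kb alone. No test was made of these descriptive values.

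**Figure D1:**
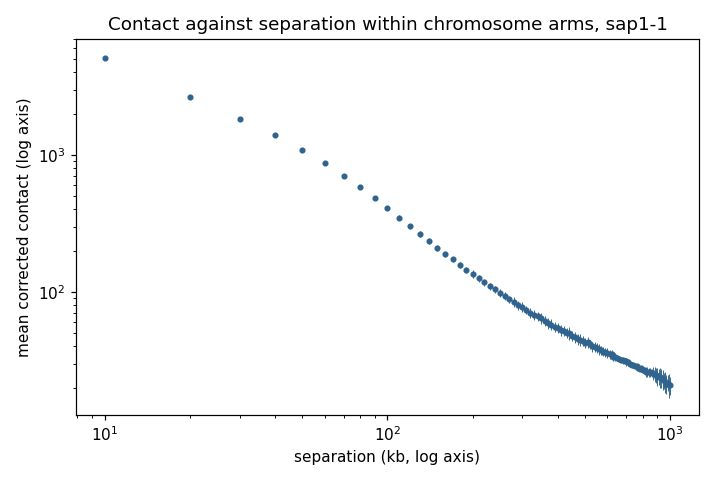
Mean corrected contact (vertical log axis) against separation in kb (horizontal log axis) within the 6 chromosome arms of the sap1-1 map, with bars of 1 SD over arms. Contact falls from 5084 at 10 kb to 20.9 at 1000 kb.

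The centromeres of the 3 chromosomes lay in contact, as did the ends of chromosomes I and II. Contact between windows reaching 50 kb to either side of the centromere midpoints was 23.2 ± 4.16 times the inter-chromosomal mean of arm bins (SD, n = 3 pairs). Centromeres I and II had the lowest fold (18.4, interval 18.0 to 18.9, 6563 reads), and I and III the highest (26.0, interval 25.3 to 26.8, 4844 reads). The terminal windows of I met those of II at 31.2 ± 11.3 times the mean (SD, n = 4 pairs), from 20.2 for the right end of I with the left end of II to 47.0 for the left end of I with the right end of II. The opposite ends of chromosome I met each other at 36.4 times that mean and those of II at 40.3. None of 10000 random placements of arm windows reached either mean fold, the middle 95% of them lying at 0.72 to 1.66 for centromeres and 0.73 to 1.30 for ends. Windows of 100 kb gave 11.8 for centromeres. Reads without the correction gave 13.3 for centromeres and 15.6 for ends, both above all random placements. Of their 30-base sequences, bins I 10001, I 5560001 and II 4490001 share 59.7%, 94.1% and 71.6% with ends of another chromosome. Over 7 alternatives, among them leaving out end bins that share sequence, the fold between ends ran from 15.6 to 35.5. Centromere bins with shared repeats were kept, so reads placed at the wrong copy cannot be told apart from contact between centromeres.

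Centromeres and ends met far less, and only the ends of the shorter arms of I and II stood above the inter-chromosomal mean. The right end of I met centromere II at 2.32 (interval 2.12 to 2.54) and centromere III at 4.399 (4.02 to 4.81). The left end of II met centromere I at 2.55 (2.33 to 2.78) and centromere III at 2.30 (2.001 to 2.63). These ends close arms of 1808 kb and 1622 kb. The ends of the longer arms, 3771 kb and 2917 kb, had folds of 0.76 to 0.96. The mean over the 8 pairs was 1.89 ± 1.26 (SD), and 5 of 10000 random placements were as high. It was inside the random range without the 5% of bins with the fewest reads (1.29, percentile 96.4) and with windows of 100 kb (1.204, percentile 91.9). Without the correction it was 0.869, at percentile 15.9.

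**Figure D2:**
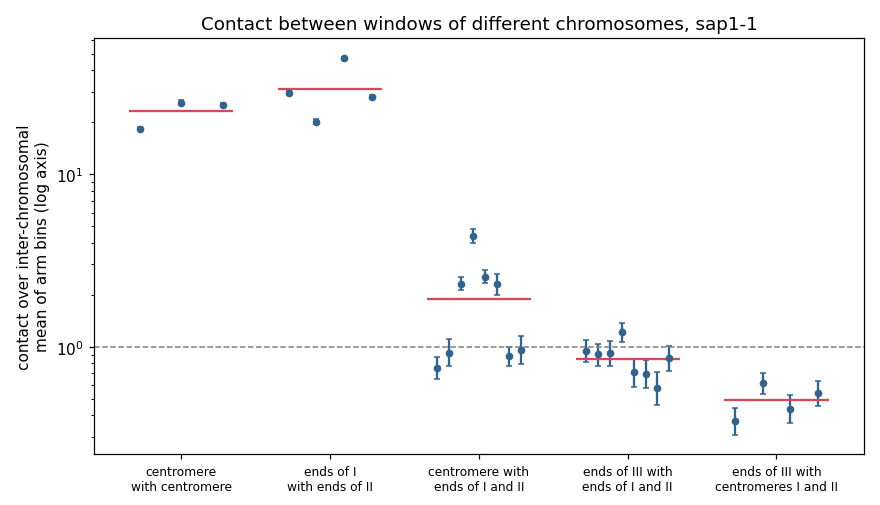
Contact between windows of different chromosomes over the inter-chromosomal mean of arm bins (vertical log axis, no unit) for 5 kinds of window pair; points are pairs with 95% Poisson intervals, red lines are means. Centromere pairs average 23.2 and pairs of ends of I with ends of II average 31.2, while the ends of III lie near or under 1.

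The end windows of chromosome III, which border the ribosomal DNA repeats, did not share these high contacts. Bins beyond these windows are blank in the map, so contact of the telomeres of III themselves was not measured. Their contact with the ends of I and II was 0.854 ± 0.195 times the inter-chromosomal mean (SD, n = 8 pairs), at percentile 17.7 of random placements. The left end of III met the right end of II at 1.21 (interval 1.06 to 1.38, 231 reads), the highest of the 8. Contact with centromeres I and II was 0.489 ± 0.108 (SD, n = 4 pairs), with 13 of 10000 placements as low. The ends of III met each other at 1.81 (interval 1.60 to 2.04), at percentile 53.3 of windows on opposite arms. The low contact with centromeres was not past the random range with windows of 20 kb (0.687, percentile 9.20) or 100 kb (0.791, percentile 14.6). Contact with the other ends was 0.477 without the correction, lower than all random placements. Contact of the ends of III with each other was unstable, being 5.33 with windows of 20 kb (percentile 97.45) but under the random range without the 5% lowest bins (0.883), with windows of 100 kb (1.15) and without the correction (0.824).

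Arms of different chromosomes lay side by side at matched distances from their centromeres. Across 469200 inter-chromosomal bin pairs, contact and the difference in distance had a Spearman rho of -0.41, ranging from -0.35 for I with II to -0.50 for II with III. Pairs within 100 kb of matched distance met 2.13 times as much as pairs 1000 kb or more apart. The arms of 1 chromosome met each other 1.51 ± 0.125 times as much as arms of different chromosomes at the same distances (SD, n = 3 chromosomes), with 1.42 for I, 1.46 for II and 1.65 for III. Bin pairs are not independent, so no p-value is given.

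The study asked about contacts of chromosome ends with chromosome arms in this mutant, and 13 of 1068 arm bins met the ends of other chromosomes at 2 times or more the running median of their neighbours. Of these, 7 adjoined one another on chromosome II, from 2090001 to 2150001, around the mating-type genes. The highest was bin 2130001 with mat3-Mc and mat3-Mi (6.68-fold, interval 6.18 to 7.20, 673 reads). Its neighbour 2120001, with the proteasome subunit gene rpt6 and the ribosomal protein gene rpp202, had 3.86, and 2110001 with mat1-Mc and mat1-Mi had 3.25. Bin 2110001 held 25861 reads, the fewest of the 13 bins, where the median over all bins was 58761.5. It has 0 HindIII sites in the reference, so 1 fragment spans it and its value may not be independent of its neighbours. Bins 2140001 (tam9, rpl401), 2150001 (atg2402, npl4), 2100001 (sui1, nif1) and 2090001 (edc3, mas2) had 2.94, 2.48, 2.26 and 2.11.

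The other 6 bins lay at 4 places. Bin 2660001 of II, with the small heat shock protein gene hsp16 and with mic60 and ric8, had 3.54-fold contact (interval 3.20 to 3.90, 398 reads), the next bin 2670001 with the DNA repair nuclease gene rad13 and fma1 had 2.94, and 2680001 with syf2 and smf1 had 2.05. Bin 4510001 of I, with mei2, whose RNA-binding protein starts meiosis, and omt2, had 2.34 (interval 2.11 to 2.59, 376 reads). Bin 310001 of II with arg7 and dal52 had 2.24, and bin 1940001 of I with aru1 and avt3 had 2.09 (interval 1.70 to 2.54, 100 reads). The remaining 7 of the 20 highest bins had 1.82 to 1.97, among them 210001 and 200001 of III with the hexose transporter genes ght5 and ght6, and also dga1 and mug146 (1.85 and 1.84). The rest were on II at 2700001 (str1, mrpl39), 300001 (mug89, nrs1), 1320001 (erg32, mis19), 320001 (car1, gor2) and 3010001 (gsf1, slm9). With internal arm windows in place of the ends, none of 100 draws gave a bin at 2 times. Those windows were drawn apart, while the ends meet each other, and the correction gives every bin the same sum. The draws are therefore a weak background. The count depended on the settings, being 22 with end windows of 20 kb, 8 with 100 kb, 30 with a wider running median, 7 with the ends of III added, 64 at 1.5 times and 6 without the mating-type bins.

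**Figure D3:**
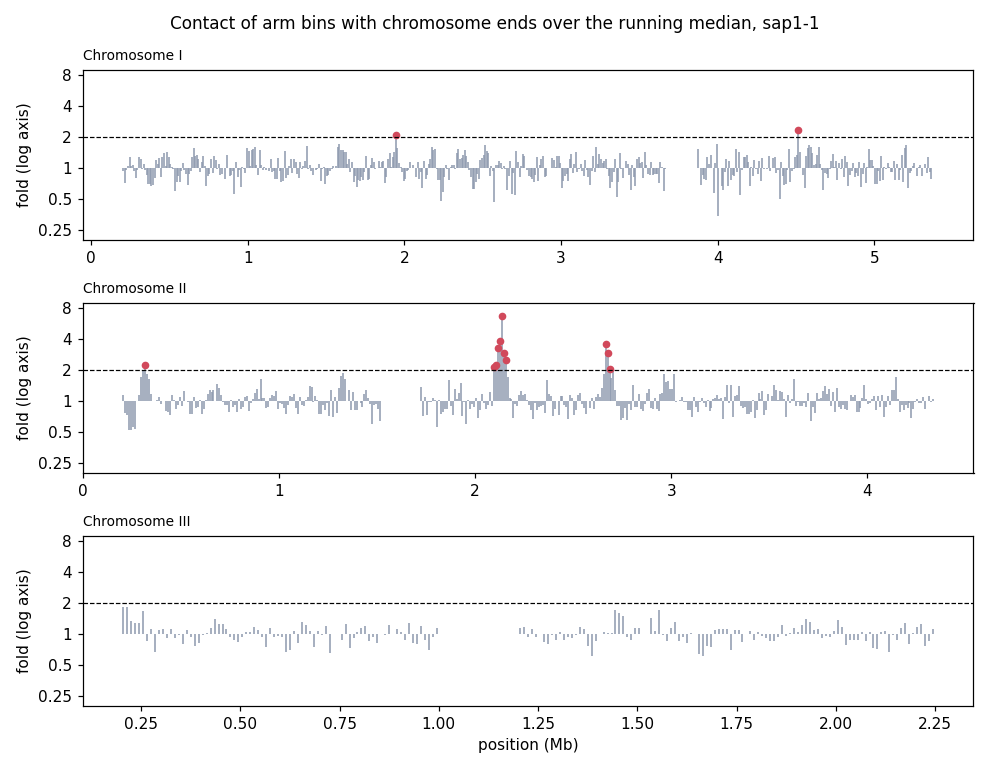
Contact of each of 1068 arm bins with the ends of I and II on other chromosomes over the running median (vertical log axis, fold) along the 3 chromosomes (horizontal axis, Mb); red points mark the 13 bins at 2 times or more and the dashed line marks 2. The highest point is the mat3 bin of II at 6.68.

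Telomere repeats inside the arms, the kind of site bound by the telomere protein Taz1, did not mark bins that met the ends more. A pair of GGTTACA copies on 1 strand within 100 bp was found in 3 arm bins. Their folds with the ends were 0.556 for I 910001 (irs4, rpl44; 43 reads), 1.22 for II 650001 (dsc1, hsp3103; 102 reads) and 0.882 for III 2040001 (cox13, cti1; 78 reads). Their median log2 ratio was -0.18 (SD 0.57), at percentile 24.1 of random arm bins, and 3 bins allow no fine statement. The bin of taz1 itself had 1.44-fold contact with the ends and 0.786 with the centromeres, and that of sap1 had 0.754 and 1.15. The bins of the end-linked helicase genes tlh1 and tlh2 are blank in the map.

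The mating-type region, whose silent mat2 and mat3 cassettes are packed as heterochromatin, met the ends and the centromeres of other chromosomes in excess. The mat3 bin, 2130001 on II, had a log2 ratio of 2.74 with the ends, the highest of 1068 arm bins, from a fold of 2.66 with the left end of I (interval 2.14 to 3.28, 89 reads) and 8.78 with the right end (8.09 to 9.53, 584 reads). Within the right end the fold was 5.04 in bin 5520001 and 9.57 to 10.1 from 5540001 outward. With the centromeres the log2 ratio was 1.47, again the highest of all arm bins, with folds of 2.501 for centromere I (interval 2.18 to 2.86) and 2.82 for centromere III (2.43 to 3.26). Contact with the right end of I and with both ends combined was lower on both sides, whereas the left end of I met bin 2110001 at 2.67 and centromere I met bin 2140001 at 2.65, no less than the mat3 bin. At 2080001 the fold with the ends of I was 0.820 and 0.977, while that with centromere I was 2.92 (interval 2.57 to 3.30) and with centromere III 1.28 (1.01 to 1.60). The log2 ratio with the ends was 1.41 without the right end of I, no longer the highest of the arm bins, and 1.79 without end bins that share sequence with other ends. It was 2.12 with windows of 100 kb and 2.15 without the correction. The log2 ratio with the centromeres ran from 0.91 to 1.52 over 5 alternatives and moved by less than the spread in 2 of them.

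**Figure D4:**
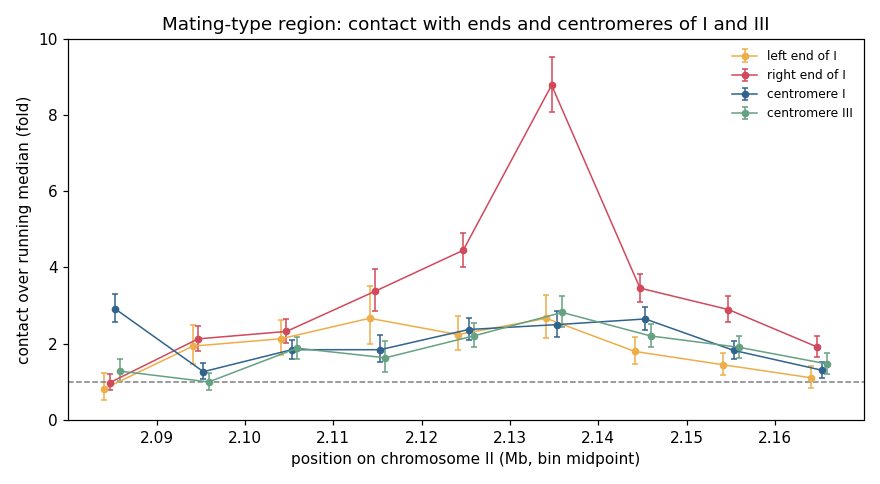
Contact over the running median (vertical axis, fold) of bins of chromosome II around the mating-type region (horizontal axis, Mb) with the ends of I and with centromeres I and III; bars are 95% Poisson intervals. The right end of I peaks at 8.78 in the mat3 bin, where the other 3 targets lie between 2.501 and 2.82.

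Among the 10 lists of loci, tRNA genes, ribosomal protein genes and long terminal repeats (LTRs, the remains of retrotransposons) met the ends slightly less than random arm bins did. Of 97 tRNA gene bins, 61 lay under the running median (median log2 ratio -0.09, SD 0.34, percentile 1.64). Of 111 bins with ribosomal protein genes, 73 lay under it (-0.14, SD 0.36, percentile 0.05), and of 148 LTR bins, 87 did (-0.08, SD 0.40, percentile 1.82). The tRNA call held under 5 of 10 alternatives, that of LTRs under 7 and that of ribosomal protein genes under 8. With the ends, the 5S rRNA genes (0.04), Tf2 retrotransposons (-0.07), histone genes (0.05), meiotic genes (0.00), glycolytic genes (-0.11) and heat shock genes (0.01) lay inside the middle 95% of random sets. Tf2 elements fell under that range without the 5% lowest bins (-0.29), with windows of 20 kb (-0.38) and without the correction (-0.84). With the centromeres all 10 lists lay inside it, from -0.06 for telomere repeat bins to 0.03 for LTRs. Over all 35 tests of lists and boundary features, 9 lay outside that range, where chance gives 1.75. The tests share bins and 1 map, so these counts do not measure how far the calls exceed chance.

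The 5S rRNA genes met each other more across chromosomes than random bins did. Their contact was 1.12 times that given by distance from the centromeres (368 pairs, percentile 99.7), LTRs had 1.02 (7172 pairs, percentile 99.6) and histone genes 1.24 (15 pairs, percentile 98.2). Of the 368 pairs of 5S bins, 212 were above 1, with a median of 1.05 and a highest of 3.33. Sequence shared between members of a list was not examined, so reads placed at the wrong copy cannot be told apart from contact here. The histone value came from 1 pair of bins, hhf2 and hht2 on II with hta1 and htb1 on III (3.31, interval 2.64 to 4.10, 84 reads), and was 0.965 without it (percentile 58.0). Glycolytic genes had 1.24 (percentile 97.0), Tf2 elements 1.11 (92.6), tRNA genes 1.03 (92.5), ribosomal protein genes 1.00 (51.8), meiotic genes 1.05 (71.6), heat shock genes 0.953 (25.7) and telomere repeat bins 1.11 (66.7). Without the correction, 5S rRNA genes were inside the random range (1.04, percentile 62.6), LTRs fell on its other side (0.899, percentile 0.35), and Tf2 elements were far under it (0.469, percentile 0.05).

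The members of the short lists had folds with the ends on both sides of 1. Among histone genes, hht3 and hhf3 shared a bin at 1.42 (hhf3 also reaches a bin at 1.28), hta2 had 1.21, hta1 and htb1 1.04, hhf1 and hht1 0.876 (hht1 also 0.792), and hhf2 and hht2 0.811. Among meiotic genes, num1, also known as mcp5, spanned bins at 1.05 and 1.64, spo5 had 1.19, crs1 1.05, ssm4 0.999, mcp7 0.940, mug8 0.625 and mei4, which encodes a meiotic transcription factor, 0.591. The cohesin gene rec8 spanned bins at 0.750 and 1.00.

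Boundaries between contact domains lay at 199 bins, with a median spacing of 50 kb (interquartile range 40 to 70, n = 193) and a median depth of 0.27 on the log2 scale, and maps simulated without domains held a median of 46 such minima. Convergent gene pairs, whose 3' ends face each other, were present in 189 of the 199 boundary bins, or 94.97%, against a median of 80.4% for shifted boundaries (middle 95% from 74.9 to 85.4). No shift of 10000 gave as many. A tRNA gene was present in 15.1% against 8.54% (4 shifts as high), and a ribosomal protein gene in 14.1% against 10.6% (percentile 97.7). LTRs (15.6%, percentile 75.3) and the most AT-rich bins (7.04%, percentile 20.5) were inside the random range. The ribosomal protein call was lost under all 7 alternatives. Without the correction there were 335 boundaries, and the tRNA share was 9.55%, inside the random range.

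The deepest boundary was at II 150001 (0.99 on the log2 scale) beside mal1 and urh1, then I 3970001 with trm5 and mug132 (0.72) and III 1310001 with the spindle checkpoint kinase gene bub1 and the adenine synthesis gene ade6 (0.70). The mat3 bin came next (0.64) and was the only one of the 10 deepest without a convergent pair. The reference used has no mat2 genes. Whether it lacks sequence that these cells carry near this bin, which would also lower contact across it, was not tested. The others of the 10, at 0.54 to 0.64, were III 1180001 (tho1, coa4), II 600001 (new20, rps1701), II 4430001 with no named gene, II 1530001 (rfc5, yhm2), II 740001 (mdm35, rti1) and I 5320001 (uaf2, ski7 and hsp9). Depth was taken from the higher flank, which faced a nearby chromosome end at II 150001 (score 0.58) and II 4430001 (0.54). It faced a nearby centromere at III 1180001 (0.70), I 3970001 (0.48) and II 1530001 (0.44). Whether a rise of the score towards ends and centromeres gave these depths was not tested. Below its lower flank III 1180001 was only 0.032 deep, and II 4430001, II 1530001 and II 600001 were 0.13 to 0.16 deep.

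Of 355211 pairs of arm bins on different chromosomes, some had many times the contact given by their distances from the centromeres. The highest was I 2240001, with the microtubule plus-end protein gene mal3 and with pof14, and III 810001 with gir2 and fil1, at 7.93 times (interval 6.42 to 9.68, 96 reads). The same bin of III also met I 1640001 (gid7, apc11) at 6.88 (62 reads), and all 3 bins hold tRNA genes. I 3370001 (alp31, rmt2) met III 1590001, with fmd3 and the alcohol dehydrogenase gene adh1, at 7.32 (49 reads). II 1310001 (kap109, ips1) met III 1450001 (gpi8, cbl1) at 5.20 (134 reads), and the pairs around it averaged 3.57. For the other 9 pairs the surrounding bins averaged 0.77 to 1.58, so each stood alone. I 1950001 (pcs2, hsr1) met III 980001 (map2, sws2) at 5.46 (28 reads). I 930001 (erg31, ssl3) met II 1100001 (cyp3, sks2) at 5.68 (42 reads), and these bins share 5 sequences of 30 bases. The other 4 of the 10 highest ratios rested on 4 to 12 reads. They were I 3990001 (pfl2 and Tf2-5) with III 2000001 (ptc1, ams2) at 6.02 (interval 1.64 to 15.4), II 510001 (cti6, rps29) with III 530001 (tcb2, eft202) at 5.94 (3.07 to 10.4), I 840001 (wss1, sst1) with III 530001 at 5.00 (2.40 to 9.19), and I 1840001 (fur4, uck2) with II 1440001 (nrk1, prp5) at 4.53 (1.82 to 9.32). Poisson counts alone would give 1707, 0.534, 16.6 and 392 pairs of as small a probability among all pairs, so these 4 were not told from counting noise. For the 6 pairs with 28 reads or more that number was at most 6.3e-07.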

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

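The alternatives with uncorrected reads, without the mating-type bins or the right end of I, with mat1 added, with boundaries deep on both flanks and without 1 histone pair were chosen after seeing the data. Of 338 alternative values, 279 were counted as kept. Values of lists and boundary features had only to keep their call or their lack of one. Counts had to stay within 1.5 times, and other values to move by less than the spread, with window values also keeping their call. Lists and features without a call made 163 of 172, and the other results, telomere repeat bins with ends included, 116 of 166. Results with values under all alternatives run that stayed so were the excess of convergent pairs at boundaries (87.8% to 96.6%), contact between arms of 1 chromosome (1.44 to 1.51), near over far contact (1.70 to 2.15) and telomere repeat bins (-0.22 to 0.05). Lists without a call gained one in 9 values, mostly for Tf2 elements and glycolytic genes, such as Tf2 elements with the ends (-0.29, -0.38 and -0.84). Where values changed, the cause was not tested, except that a wider window or a lower threshold changes the bins counted. Without replicates, moves were judged against the spread over arms, windows or bins. Leaving out replicates was not run, since there is 1 map, and 20 kb windows left no bins at centromere III.

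Without the correction, folds were 13.3 between centromeres, 15.6 between ends, 0.869 between centromeres and ends (reversed), 0.477, 0.334 and 0.824 for the ends of III with other ends, with centromeres and with each other, alignment was -0.32, tRNA and ribosomal protein bins with ends had -0.058 and -0.10, mat3 with centromeres 1.01, contact among 5S genes was 1.04 and among LTRs 0.899 (reversed), among Tf2 elements 0.469, boundaries numbered 335 and 9.55% held a tRNA gene. Re-balancing gave -0.078 for tRNA genes with ends. Leaving out low bins gave -0.025 for LTRs, 1.29 for centromeres with ends and 0.883 for the ends of III with each other. Windows of 20 kb gave 0.687 for the ends of III with centromeres, 5.33 with each other, 22 arm bins, -0.090 for tRNA genes and -0.067 for ribosomal protein genes. Windows of 100 kb gave 11.8 between centromeres, 1.204 for centromeres with ends, 0.791 and 1.15 for the ends of III with centromeres and with each other, 8 arm bins, -0.060 for tRNA genes and 0.91 for mat3 with centromeres. A running median over 200 kb gave 30 arm bins and -0.11 for tRNA genes. With the ends of III there were 7 arm bins and LTRs had -0.018, and with ends of the same chromosome LTRs had -0.044. There were 64 arm bins at 1.5 times and 6 outside the mating-type region. The contact of mat3 was 1.41 with the ends without the right end of I, and 1.17 with centromeres when mat1 was added. Histone genes without the highest pair had 0.965. The within-chromosome share was 77.4% without adjacent bins, and the exponent -1.16 to 100 kb and -1.20 beyond. Ribosomal protein genes at boundaries had 13.6% after re-balancing, 14.8% without low bins, 13.1% and 13.6% with insulation windows of 30 and 100 kb, 14.8% at depth 0.2, 14.5% at 0.1 on both flanks and 12.8% uncorrected.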

Other observations

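Every test below except those of counting noise at the 2-times bins, gene number, HindIII sites with reads, and noise at all boundaries was chosen after the result was seen. The outermost 40 kb of the right end of chromosome I, bins 5530001 to 5560001, differed from the bins just inside in contact with mat3 and centromeres. These bins hold gdt1, pdc102, ftm3 and ftm4. They met the ends of II at 14.2 to 26.8 times the inter-chromosomal mean, and the 6 bins from 5470001 to 5520001, with hry1, sul2, yhb1 and pfl9 among their genes, at 23.3 to 40.6, so the ranges overlap. With the mat3 bin they did not, the outer bins having 14.8 to 24.96 times the mean (45 to 187 reads) and the inner bins 4.09 to 6.41. With centromeres II and III the outer bins had 2.71 to 4.11 times, and the inner bins 1.36 to 2.07. The inner stretch was chosen after its values were seen.

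Adjacent bins of this outer block had high corrected contacts, 7568 (6007 reads) and 8776 (6443 reads), where 1053 pairs of adjacent arm bins had a mean of 4982 ± 740.4 (SD over pairs), with 3 and 0 of them as high. Those arm bins lay at least 200 kb from a chromosome end, and adjacent bins of the other ends were not examined. The high values therefore cannot be told apart from what outermost bins in general show after the correction. The outermost pair had 10820 but only 1894 reads, and its outer bin shares 94.1% of its 30-base sequences with ends of another chromosome. The pair 5520001 and 5530001 had 3926, and the pair before it 3955. On chromosome II, bin 2080001, with the ribosomal protein gene rps21, the kinetochore protein gene sim4 and aim21, met centromere I at 2.92 times its running median (interval 2.57 to 3.30, 254 reads) and centromere III at 1.28 (interval 1.01 to 1.60, 78 reads), without an excess with the ends.

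The mating-type region met the ends and centromeres of other chromosomes. Wrong placement of reads of sequence shared with ends or centromeres was argued against for 6 of its 7 bins, mat3 included. These share no 30-base sequence with any bin within 100 kb of an end or centromere, while bin 2090001 shares 0.562% and stays open. Sequence shared between bins of the region, such as the mat1 bin 2110001 and the mat3 bin, was not compared. Reads of 1 such bin placed at the other therefore stay open. Centromere-like repeats missing from the reference were argued against by folds of the mat3 bin of 2.54 (interval 2.22 to 2.90) with centromere bins free of centromere repeats, and 5.23 (interval 4.63 to 5.90) with the 5 end bins that share under 1% of their sequence with other ends. Of these end bins, 5520001 and 5540001 of the right end of I had 5.04 and 9.70. Those of the left end had 3.00, 1.59 and 1.17 (27, 9 and 10 reads), so for ends the argument rests mainly on the right end. Placement of the outermost bins of I within 50 kb of the region in all cells of this strain was argued against, since their highest contact with the mat3 bin was 311 and 0 of 1030 bin pairs 50 kb apart on an arm were as low (lowest 588). A distance of about 100 kb, where 44 of 1000 pairs were as low, or a rearrangement in part of the cells stays open, so that heterochromatic regions meet in these cells is only a hypothesis, and no control strain was given to tell whether sap1-1 has a part in it.

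The 6 arm bins at 2 times outside that region, such as those of hsp16 and mei2, exceeded counting noise, since 0 of 1000 simulated profiles had as many and the highest had 1. With internal windows as bait the median fold of the 6 bins was 1.00. The correction gives every bin the same sum, so this value could hardly differ and does not decide whether the correction raised them. These 6 bins held 40415 to 64565 reads, where the median over all bins was 58761.5. None held a wide telomere repeat site (0 of 6, where 68 of 1068 arm bins did). What brings them near the ends stays open, and with 1 group no biological explanation was tested.

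Convergent gene pairs lay at 94.97% of boundaries. More genes per boundary bin (4.43 against 4.09) and HindIII sites with reads were argued against, since the share was at percentile 100 of random bins matched on either, with upper random bounds of 87.9% and 85.4%. Counting noise gave a median of 46 minima (39 to 51) in maps simulated without domains, so about that many of the 199 cannot be told apart from noise at this depth of sequencing. Among minima at least 0.2 deep noise gave 10 (highest 14) of 149, and there the share with a convergent pair was 96.0%. No biological explanation was tested for this pattern.

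A shared position in the nucleus may link the arm bins that meet the ends. If so, they should also meet one another, and the 56 bins at 1.5 times outside the mating-type region did so at 1.16 times the expectation (921 pairs), above all random sets, whose upper bound was 1.05. The 6 bins at 2 times had 1.78 (8 pairs). Some of these bins adjoin one another, while the random sets were single bins drawn along each arm, so the random range may be too narrow. The bins were also chosen and tested on the same map, so a shared position remains a hypothesis.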
